A study of Drosophila melanogaster with 4 samples.

How the data were processed

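Total RNA of dissected adult intestines was sequenced after standard Illumina library preparation, per the labels' protocols, from 2 libraries of wild-type flies and 2 of flies with RNAi against CG5789. The values used were raw read counts per gene as deposited, 1 column per library, whole numbers without normalization, which sum to between 11294882 and 30537063 per library. The submitters' processing notes name FastQC, STAR and the BDGP6 assembly. Tool versions, the counting tool, its strand setting and the annotation release were not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies carry an unknown split. Genes were listed by FlyBase identifier, of which 17405 were matched to a symbol and 105 were not, and positions came from a BDGP6 gene annotation.

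Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 9637 of 17510, libraries were scaled by TMM, and the quasi-likelihood test (estimateDisp, glmQLFit with robust estimation, glmQLFTest) compared the genotypes over all 4 libraries with no other term. Calls used a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The comparison, the gene lists, the naming rule and the first group of alternative settings were set before the data were examined. The naming rule took, among genes past the threshold with a mean of at least 5 CPM and no overlap between genotypes, the 8 higher and 8 lower with the largest fold change, up to 3 called members of each list, up to 2 members with the smallest p where fewer than 2 were called, and always CG5789, w and tio. Genes named only from the fit with the library set were chosen after their values were seen.

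A total of 30 gene lists (626 names, of which 3 matched no identifier) covered cell types, digestive and transport functions, immunity, stress, metabolism and markers of other tissues. The 29 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. With an estimated correlation none of the 9 calls held, and the smallest adjusted p was 0.478; by fry it was 0.281 for change in 1 direction, and 2 lists were called for change in either direction. Camera compares a list with all other genes, and fry tests the list by itself. In simulated counts with the means and library sizes of these data and no set difference, the test without the set term recovered 2.0%, 58.0%, 96.0% and 100.0% of genes changed 2-fold, 4-fold, 8-fold and 16-fold (50 genes each of 9637), with 6 false calls. With a simulated set difference and the set as a term it recovered 78.0%, 100.0%, 100.0% and 100.0%, with 4 false calls. In both simulations every gene had the same dispersion. These shares can therefore be too high for genes that vary more between libraries, and the shares without the set term also leave out the set difference of these data. A simulated list raised 2-fold had a camera adjusted p of 2.10e-08 with the preset correlation and 0.476 with an estimated one. The latter missed that list, and with the preset correlation 0 of 20 unchanged lists were called. The simulated genes were drawn independently of each other, which favours the preset correlation. This simulation therefore cannot show which setting is right for lists whose genes vary together.

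The first group of alternative settings was RLE and upper-quartile factors, library size alone, no count filter, a minimum mean of 5 CPM, each library left out, non-robust estimation, the 20 most abundant genes left out, DESeq2 1.42.0 and limma-voom. Where a left-out library left 1 library in a genotype, that library was assumed to vary like the others. After the data were examined, a term for the library set (wild type 1 with RNAi 1, wild type 2 with RNAi 2, from the sign of the leading principal component) was added, with edgeR, DESeq2, limma-voom and library size alone, together with thinning to the smallest total and removal of a loess trend on transcript length (span 0.5) per library. Fits with the set term could not be repeated without a library, since no residual degree of freedom is left. Exact 95% intervals of count ratios between libraries or groups were binomial and cover counting error only, as do floors of 3 counts.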

Results

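RNA from dissected adult Drosophila melanogaster intestines, with the Malpighian tubules and crop removed, was sequenced from 2 genotypes. The first was wild type and the other carried a transgenic RNAi line of the National Institute of Genetics stock collection against CG5789, the gene taken here as the fly counterpart of the human chloride channel gene CFTR and now named Cftr. Each genotype had 2 libraries, and the comparison asked how gut expression differed between them. The driver of the RNAi was not given in the sources used here. None of the libraries is labelled as a control for the transgene, the driver or the line background. A difference between the genotypes therefore cannot be told apart from an effect of any of these. Libraries of each genotype were numbered here in the order of deposit, since the labels give no number. Total counts per library were 30537063 and 11294882 for wild type 1 and 2, and 30252763 and 23674485 for RNAi 1 and 2. Mitochondrially encoded genes took 4.55% and 6.22% of the wild-type counts and 6.07% and 6.80% of the RNAi counts. Of 17510 genes in the table, 1907 had no count in any library and 9637 were tested. Nothing in the labels says that the 2 libraries of a genotype came from separate groups of flies, so p-values measure only the spread between these libraries, which may be technical.

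The targeted gene was not uniformly lower in the libraries labelled RNAi. Cftr, a member of the ABC transporter C subfamily, had 13.8 CPM (TMM-scaled counts relative to the library total) in RNAi 1 and 17.5 CPM in RNAi 2, against 13.8 CPM in wild type 1 and 43.4 CPM in wild type 2. Its counts were 432 and 429 in the RNAi libraries and 398 and 483 in the wild-type libraries. The gene (FBgn0039207) lies on the minus strand of chromosome arm 3R at 24536204 to 24543914 of the BDGP6 assembly, and its annotated span overlaps ana1 on the other strand, so that without strand information reads of the overlap cannot be assigned. The fitted log2 fold change, RNAi relative to wild type, was -0.86 (SE 0.57), with an edgeR adjusted p of 1.0. Without wild type 2 the log2 fold change was 0.20, so the lower level rested on that library. Wild type 1 and RNAi 1 thus had the same Cftr level, which does not show which library, if any, goes against its label. Every direction given here is for libraries as labelled.

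Expression separated the 4 libraries along 2 axes. The leading principal component, with 52.6% of the variance, placed wild type 1 and RNAi 1 (set 1) apart from wild type 2 and RNAi 2 (set 2), while the next component, with 34.3%, placed the RNAi libraries apart from the wild-type libraries. Correlations of log2 CPM across genes, which are not independent replicates, were 0.970 within each set, 0.961 between the wild-type libraries and 0.956 between the RNAi libraries, and 0.948 and 0.940 between libraries that shared neither. Within set 1 the Cftr level of RNAi 1 was 1.01 times that of wild type 1 (95% exact interval 0.875 to 1.16), and within set 2 RNAi 2 was at 0.403 times wild type 2 (0.353 to 0.460), with intervals that cover counting error only. With the set as a term in the model the log2 fold change of Cftr was -0.65 (SE 0.35, edgeR adjusted p = 0.442). The labels name no batch: the sets were read from the counts themselves, and each set holds 1 library of each genotype.

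**Figure D1:**
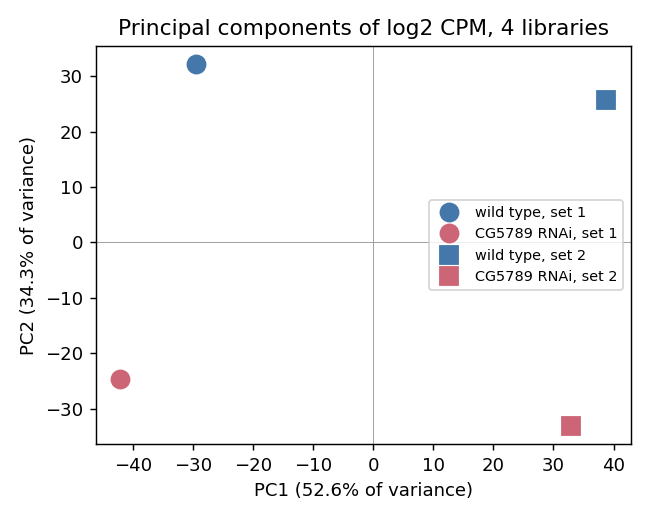
Principal components of log2 CPM over the 9637 tested genes, one point per library, coloured by labelled genotype and shaped by library set. PC1 (52.6% of variance) parts set 1 from set 2 and PC2 (34.3%) parts the genotypes.

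The genes that differed between the libraries labelled RNAi and wild type included a heat-inducible chaperone gene, gut lysozymes and a digestive protease. Hsp70Bb, an inducible chaperone of the Hsp70 family, had 1230 and 919 counts in the RNAi libraries against 3 and 1 in wild type, a ratio of 386 (95% exact interval 151 to 1418, counting error only). The lysozyme genes LysC, LysD and LysB were 90.2-fold, 64.7-fold and 46.4-fold higher, and LysD reached 2942 and 4022 CPM in the RNAi libraries against 77.9 and 29.4 CPM in wild type. Task6, a potassium channel gene, was 29.0-fold higher, Crys, which encodes drosocrystallin, was 21.1-fold higher, CG10725 was 18.3-fold higher and the cytochrome P450 gene Cyp6a14 was 15.6-fold higher. Jon44E, a Jonah-family gut serine protease, fell by 4.05 on the log2 scale, from 728 and 880 CPM in wild type to 37.8 and 59.0 CPM in the RNAi libraries.

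These genes belonged to the 12 that passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 10 higher and 2 lower, from 369 genes at an unadjusted p under 0.05. The log2 fold changes were 8.52 (SE 0.57) for Hsp70Bb, 6.49 (SE 0.60) for LysC, 6.02 (SE 0.66) for LysD, 5.54 (SE 0.64) for LysB, 4.86 (SE 0.53) for Task6, 4.40 (SE 0.51) for Crys, 4.20 (SE 0.44) for CG10725, 4.0 (SE 0.46) for CG34451, 3.96 (SE 0.44) for Cyp6a14 and -4.05 (SE 0.47) for Jon44E. The adjusted p was 0.00966 for Hsp70Bb and 0.0401 for each of the others. The remaining pair lay outside the naming rule and was named after its values were seen: Cyp12d1-d had 113 and 158 counts in the RNAi libraries against 1 and 0 in wild type (ratio 195, exact interval 34.7 to 7720), and CR40190 had no counts in the RNAi libraries against 124 and 60 in wild type, at least 85.4-fold lower by a floor of 3 counts over the group. In all 12 genes both RNAi libraries lay on 1 side of both wild-type libraries. Such separation held for 24.2% of tested genes, where chance alone gives 33.3%.

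Reads of Hsp70Bb, of the neighbouring lysozyme genes and of Cyp12d1-d can be shared with near-identical copies, LysC overlaps LysD and is annotated as a pseudogene, and Jon44E overlaps CG8586, so the split of counts among such genes is uncertain. The number of calls depended on the setting: it was 1 with upper-quartile factors or a minimum mean of 5 CPM, where Hsp70Bb alone passed, 120 without a count filter, 85 with DESeq2, and 72 without wild type 1, 72 without RNAi 1, 58 without wild type 2 and 120 without RNAi 2, with all 12 genes called in each of these last 6 fits.

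**Figure D2:**
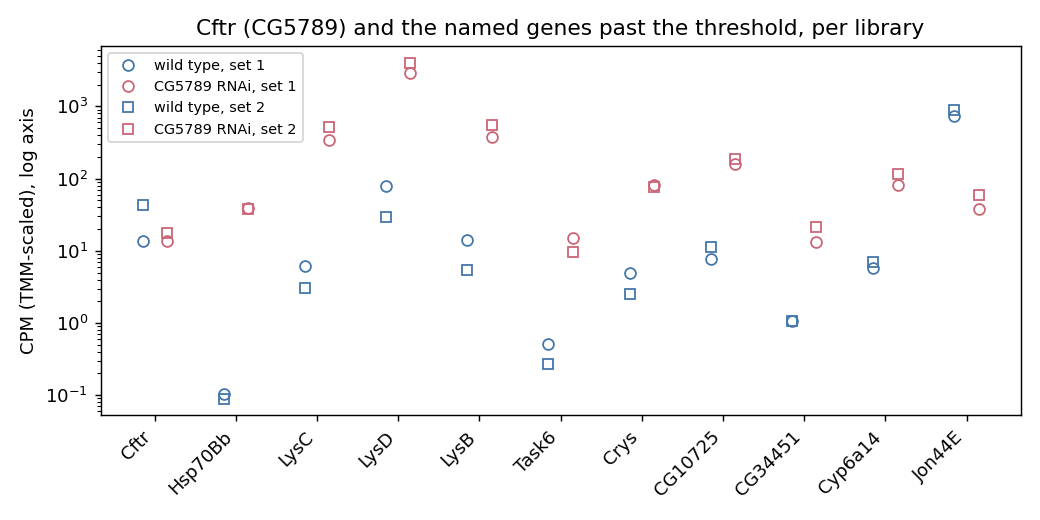
CPM (TMM-scaled, log axis) of Cftr and the 10 genes of the naming rule that passed the threshold, one point per library, coloured by labelled genotype and shaped by library set. Hsp70Bb lies at 39.4 and 37.5 CPM in the RNAi libraries and at 0.104 and 0.0898 CPM in wild type, Jon44E lies lower in RNAi, and Cftr overlaps between the genotypes.

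Many more genes separated the genotypes once the library set was a term in the model, an alternative chosen after the data were examined. In that fit 332 genes were higher and 352 lower in the RNAi libraries, 684 of 9637 tested in all, with 1710 at an unadjusted p under 0.05. The numbers of list members that passed in that fit were not tested against this share. A list with only 1 or 2 such members can lie near it. Among the calls with a mean of at least 5 CPM, 109 were at least 2-fold higher and 101 at least 2-fold lower. The biological coefficient of variation was 36.1% without the set and 14.8% with it. Of the 12 genes called without the set, 10 were called with it, while LysD (adjusted p = 0.0989) and LysB (adjusted p = 0.255) were not in edgeR, although their log2 fold changes were 6.14 and 5.56. With the set term DESeq2 called 11 of the 12 and limma-voom all 12. Because the sets were defined from the same counts and 1 residual degree of freedom was left, the p-values of this fit can be too small.

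The ratio of RNAi to wild type was also taken within each set. Over the 6760 genes with a mean of at least 5 CPM, the log2 ratios of RNAi to wild type in set 1 and set 2 had Pearson's r of 0.675 and Spearman's rho of 0.455 across genes. In 166 genes the ratio was at least 2-fold in both sets, and all 166 had the same direction in both, 90 higher and 76 lower. Hsp70Bb had log2 ratios of 7.72 and 7.76, Jon44E -4.27 and -3.90, GstD9 3.47 and 3.15, and Jon66Ci -3.02 and -3.04 in sets 1 and 2. Within a set each genotype was 1 library, and since the pairs were picked from the same counts, the likeness of the ratios is in part set by that choice: with the other pairing, wild type 1 with RNAi 2 and wild type 2 with RNAi 1, Pearson's r was -0.311 and 101 of 566 genes with at least 2-fold ratios in both pairs had the same direction.

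**Figure D3:**
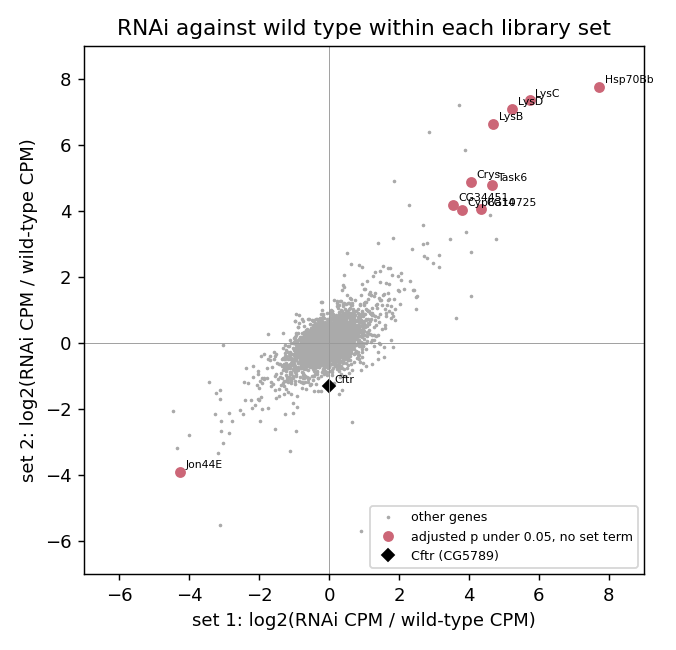
Log2 ratio of RNAi to wild-type CPM in set 1 (x axis) and set 2 (y axis), one point per gene with a mean of at least 5 CPM. Genes with an adjusted p under 0.05 without the set term are named and lie at the same sign in both sets, and Cftr lies at 0.0079 and -1.31.

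Digestive enzyme genes included members that were higher and members that were lower. Of 7 tested lysozymes, which break down bacterial cell walls, LysB, LysC and LysD were higher, and 4 were adjusted over the list alone. Of 21 tested amylases, maltases and mannosidases, the carbohydrases of the gut, 11 were higher with the set as a term and none lower. Among them were Mal-B1 at 24.4-fold, the lysosomal glucosidase homologue Gba1a at 3.37-fold, Amyrel at 3.35-fold, Mal-A4 at 2.33-fold and Amy-d at 2.19-fold. Of 26 trypsins and Jonah proteases 8 were lower and 3 higher in that fit: the log2 fold changes were -3.03 for Jon66Ci, -1.49 for Jon99Fii and -1.45 for Jon65Ai, whereas Jon99Ci and Jon25Bii rose by 1.28 and 1.10.

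By limma's camera with its preset correlation, the lysozyme list was higher (median log2 fold change 4.85, adjusted p = 6.48e-13), as was the carbohydrase list (median 0.69, adjusted p = 1.87e-08), and the protease list was lower (median -0.40, adjusted p = 7.67e-04). With an estimated correlation the adjusted p was 0.478 for all 3 lists. Without the set term no carbohydrase gene passed in edgeR, with 4 at an unadjusted p under 0.05, 2 called by DESeq2, 0 called by limma-voom and 1 adjusted over the list alone, Mal-B1, whose adjusted p over all genes was 0.0750. Without RNAi 1 and the set term, the log2 fold change of Amyrel was -0.16. Adjusted over the list alone, 2 proteases were lower without the set term, and with it 13 carbohydrases and 5 proteases were higher and 9 proteases lower. With the set term LysC (adjusted p = 0.00181) and LysP (adjusted p = 0.0468) of the lysozymes passed in edgeR, 3 adjusted over the list alone, whereas DESeq2 and limma-voom called 4 each.

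Detoxification genes included members that rose and members that fell in the RNAi libraries. In the list of glutathione transferases, which conjugate glutathione to reactive compounds, and other oxidative defence genes, 13 of 31 tested members were higher with the set as a term and 1 was lower; those higher were transferases and the peroxiredoxin Prx2. GstD9 rose by 3.32 on the log2 scale (CPM 186 and 134 against 16.7 and 15.1) and GstD10 rose 7.82-fold. Named, like Prx2, after their values were seen, GstD2 rose 18.7-fold, GstD8 7.13-fold, GstD1 6.52-fold and GstE8 3.72-fold, and the lower member was Prx6c, a peroxiredoxin, which fell by 2.60 on the log2 scale. Cytochromes P450 and glucuronosyl transferases went both ways, with 7 of 41 higher and 4 lower: Cyp6a14 rose 15.3-fold and Cyp6a23 2.10-fold, while the log2 fold changes of the lower members were -3.80 for Cyp6a17, -2.93 for Cyp6a8, -1.42 for Ugt49B1 and -0.74 for Cyp28d1.

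The glutathione transferase and oxidative defence list had a camera adjusted p of 1.67e-10 (median log2 fold change 0.93), and an adjusted p of 0.750 with an estimated correlation. Without the set term none of its members passed in edgeR over all genes, the closest being GstD9 with an adjusted p of 0.0532. At an unadjusted p under 0.05 there were 12, DESeq2 called 8, limma-voom called 1, and adjusted over the list alone 9 were higher and 1 lower. With the set term, 14 were higher and 2 lower adjusted over the list alone. The P450 and glucuronosyl transferase list was not called by camera (adjusted p = 0.333), but fry's test for change in either direction gave an adjusted p of 0.0187. Adjusted over the list alone it had 1 higher and 3 lower members without the set term, and 7 higher and 7 lower with it. Several Gst and Cyp6a genes are close tandem copies, among which the split of reads is uncertain.

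Single genes of the enterocyte, lipid and transporter lists passed. Npc1b, the midgut sterol uptake gene, rose 3.32-fold and Npc2f 1.69-fold with the set as a term, and these were the 2 of 13 enterocyte markers that passed. In the lipid list 5 of 31 members were higher, the others being Lip3, Npc2e and Agpat1, and ACC, the fatty acid synthesis enzyme acetyl-CoA carboxylase, was lower (log2 fold change -0.56). Among 30 chloride, cation and water transport genes, 4 were higher and 1 lower: the aquaporin-family genes bib (13.4-fold) and Prip (1.70-fold), the anion transporter Prestin (log2 fold change 0.67) and the cotransporter Ncc69 (0.56) rose, and the potassium channel Irk3 fell by 1.16 on the log2 scale. MRP, an exporter of the same ABC subfamily as Cftr, rose 1.82-fold and was the one of 11 such genes that passed.

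Camera called the lipid list higher without the set term (median log2 fold change 0.34, adjusted p = 0.0391; adjusted p = 0.750 with an estimated correlation), but not with it (adjusted p = 0.0635), nor without wild type 1 (0.473), and without RNAi 2 the median was -0.34 (0.910). Without RNAi 1 and the set term, the log2 fold change of Lip3 was -0.22, and without RNAi 2 that of Ncc69 was -0.36. The transporter lists were not called without the set term (adjusted p = 0.859 for ion and water transport and 0.139 for ABC subfamily C), and the latter was with it (adjusted p = 0.0472; adjusted p = 0.826 with an estimated correlation). The enterocyte list had an adjusted p of 0.396. Adjusted over the list alone with the set term, 8 lipid genes were higher and 2 lower, 5 ion and water transport genes were higher and 1 lower, and 2 ABC genes and 2 enterocyte markers were higher. Without the set term the corresponding count was 1, for bib.

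Beyond Hsp70Bb, 3 of the other heat shock and JNK genes passed, with smaller changes. Hsp83, the fly Hsp90, rose 2.46-fold (CPM 866 and 410 against 236 and 250), the co-chaperone gene stv rose 1.82-fold and puc, the JNK phosphatase, rose 1.52-fold, so that 4 of the 16 tested heat shock and JNK genes were higher with the set as a term and none lower. Camera called this list without the set term (median log2 fold change 0.33, adjusted p = 0.00638; adjusted p = 0.750 with an estimated correlation), and fry's test for change in either direction gave an adjusted p of 0.00247. The call ended without wild type 1 (adjusted p = 0.242, median 0.012) or without a count filter (0.0706). Adjusted over the list alone 1 gene, Hsp70Bb, passed without the set term, and 4 were higher and 1 lower with it. Whether the list result by fry rested on Hsp70Bb was not tested on the list itself. A smaller family of 9 heat shock genes without Hsp70Bb was chosen after the data were examined. For it, fry's test for either direction gave an adjusted p of 0.748, adjusted over families instead of lists. Camera gave that family an adjusted p of 0.0316 without the set term, and 0.562 with an estimated correlation.

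Muscle, respiratory chain and proton pump genes had median log2 fold changes of -0.47, -0.21 and -0.24, and as lists passed camera with its preset correlation, but not with an estimated one (adjusted p = 0.750 for each). Of 19 visceral and body muscle genes, 17 were lower in both sets and 4 passed with the set as a term: the log2 fold changes were -0.99 for TpnC47D, a troponin C, -0.74 for Act87E, an actin, -0.73 for up, the troponin T gene, and -0.51 for sls. Without wild type 2 and the set term, that of Act87E was 0.47. Of 30 nuclear respiratory chain genes, 18 were lower and 0 higher in both sets, and SdhA and ND-51 passed, with log2 fold changes of -0.97 and -0.91. Of 20 V-ATPase subunit genes, 15 were lower in both sets and 0 higher, and no single gene passed in edgeR (3 at an unadjusted p under 0.05 with the set term, 0 by DESeq2 and 0 by limma-voom), with VhaPPA1-1 at a log2 fold change of -0.47 (SE 0.21). Muscle genes also differed between the sets, being higher in set 2 (camera adjusted p = 0.00596), and the respiratory chain list was lower there (adjusted p = 0.00171).

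Camera adjusted p-values without the set term were 8.33e-04 for muscle, 0.0113 for the respiratory chain and 0.0237 for the V-ATPase, and the adjusted p was 0.750 for each with an estimated correlation. The muscle call ended without RNAi 1 (adjusted p = 0.667) or wild type 2 (0.681), that of the respiratory chain without wild type 1 (0.929, median 0.080) or RNAi 2 (0.284), and that of the V-ATPase without wild type 1 (0.0706), RNAi 1 (0.920) or wild type 2 (0.316). Adjusted over the list alone with the set term, 13 muscle genes and 2 respiratory chain genes were lower.

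Markers of enteroendocrine cells that passed went both ways. Among 25 such markers 3 were higher and 3 lower with the set as a term. NPF, neuropeptide F, had a log2 fold change of -0.94 (CPM 22.4 and 15.7 against 43.0 and 30.1), mirr of -0.80 and Orcokinin of -0.62, whereas CCHa1, CCHa2 and AstA rose by 0.67, 0.66 and 0.63. Of 11 stem cell and enteroblast markers, Sox21a, a regulator of enteroblast differentiation, rose 1.86-fold and mira fell by 0.61 on the log2 scale, and no one of 27 cell cycle and replication genes passed in edgeR (3 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom with the set term). In the JAK-STAT and EGFR list of 17, Socs36E, a feedback inhibitor of JAK-STAT signalling, rose 1.54-fold and TotM fell by 3.69 on the log2 scale, at 8 and 1 counts in the RNAi libraries against 104 and 5 in wild type. The posterior midgut regulator cad fell by 0.58 and was the one of 14 regional regulators that passed.

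Of the immune and barrier genes, members of the antimicrobial peptide, mucin and septate junction lists passed with the set as a term. Of 5 antimicrobial peptide genes with enough counts, Drsl2 rose by 4.47 (SE 0.45) and AttD by 1.30 (SE 0.28) on the log2 scale and Drsl3 fell by 1.99. The AttD counts separated the sets more than the genotypes, with 1.47 CPM in RNAi 1 and 30.2 in RNAi 2. None of 16 peptidoglycan recognition and Imd genes passed in edgeR with the set term (0 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom), and PGRP-SC2 had a log2 fold change of 0.33 (SE 0.20). Among 15 mucin and peritrophic matrix genes, Crys was higher, and the log2 fold changes were -1.78 for Muc14A, -1.41 for Mur18B and -0.71 for Muc68E, which fell. The septate junction gene Gli rose 1.57-fold and was the one of 20 that passed, where 684 of all 9637 tested genes passed in that fit. The amino acid transporter gene mnd fell by 0.92 as the one of 16 insulin and nutrient response genes that passed, where tobi, a glucosidase gene, had a log2 fold change of 2.22 (SE 0.44, adjusted p = 0.0526). Without RNAi 2 and the set term, the log2 fold changes of AttD and Gli were -1.74 and -0.24, and without wild type 1 that of Mur18B was 0.69. Of 13 glycolysis genes none passed in edgeR (1 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom with the set term).

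None of these hormone, progenitor, immune, barrier and metabolic lists was called by camera without the set term. The adjusted p-values were 0.859 for the enteroendocrine and for the JAK-STAT and EGFR lists, 0.211 for the stem cell, cell cycle and regional lists, 0.210 for antimicrobial peptides, 0.547 for peptidoglycan recognition, 0.878 for mucins, 0.859 for septate junctions, 0.859 for insulin response and 0.396 for glycolysis. Without the set term 1 gene of these lists passed, Crys, and adjusted over the list alone Drsl2 and Drsl3 passed too. Adjusted over the list alone with the set term, the numbers higher and lower were 5 and 3 enteroendocrine, 1 and 1 stem cell, 1 and 2 JAK-STAT and EGFR, 0 and 1 regional, 2 and 1 antimicrobial, 2 and 5 mucin, 1 and 0 septate junction and 3 and 2 insulin response genes. Median and mean log2 fold changes differed in sign for JAK-STAT and EGFR (0.038 and -0.15), ion and water transport (-0.035 and 0.14), mucins (-0.13 and 0.07), ovary genes (0.059 and -0.0099) and enteroendocrine genes (-0.033 and 0.0036).

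Of the markers of other tissues than muscle, 3 genes passed with the set as a term. None of 9 Malpighian tubule genes, 12 neuronal genes and 3 ovary genes passed in edgeR with the set term, with 2, 3 and 0 at an unadjusted p under 0.05, 0 by DESeq2 in each and 1, 2 and 0 by limma-voom. Camera adjusted p-values without the set term were 0.396, 0.211 and 0.964. Of 12 fat body and haemocyte genes, the phagocytosis receptor gene NimC1 rose 7.83-fold from a low level (CPM 4.20 and 2.89 against 0.311 and 0.718) and the yolk protein gene Yp1 rose 1.59-fold (list adjusted p = 0.211; 2 higher and 1 lower adjusted over the list alone, and NimC1 without the set term). The male reproductive tract list had 2 tested members and was not tested as a list: Est-6, an esterase of the male tract, rose 3.05-fold (CPM 4.68 and 8.73 against 2.39 and 1.53, adjusted p = 0.0025), and Acp36DE had a log2 fold change of 0.50 (SE 0.87). The sex and age of the adult flies were not given in the sources used here. Of 6 genes that can mark transgenes or line background, w, the white gene used as a marker in many fly transgenes, rose 1.69-fold (CPM 49.9 and 81.5 against 31.1 and 45.6) and was the one that passed (list adjusted p = 0.535; 1 adjusted over the list alone). Another gene of that list, tio, had a log2 fold change of 0.089 without the set term (SE 0.83), at 10 and 25 counts against 12 and 10.

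**Figure D4:**
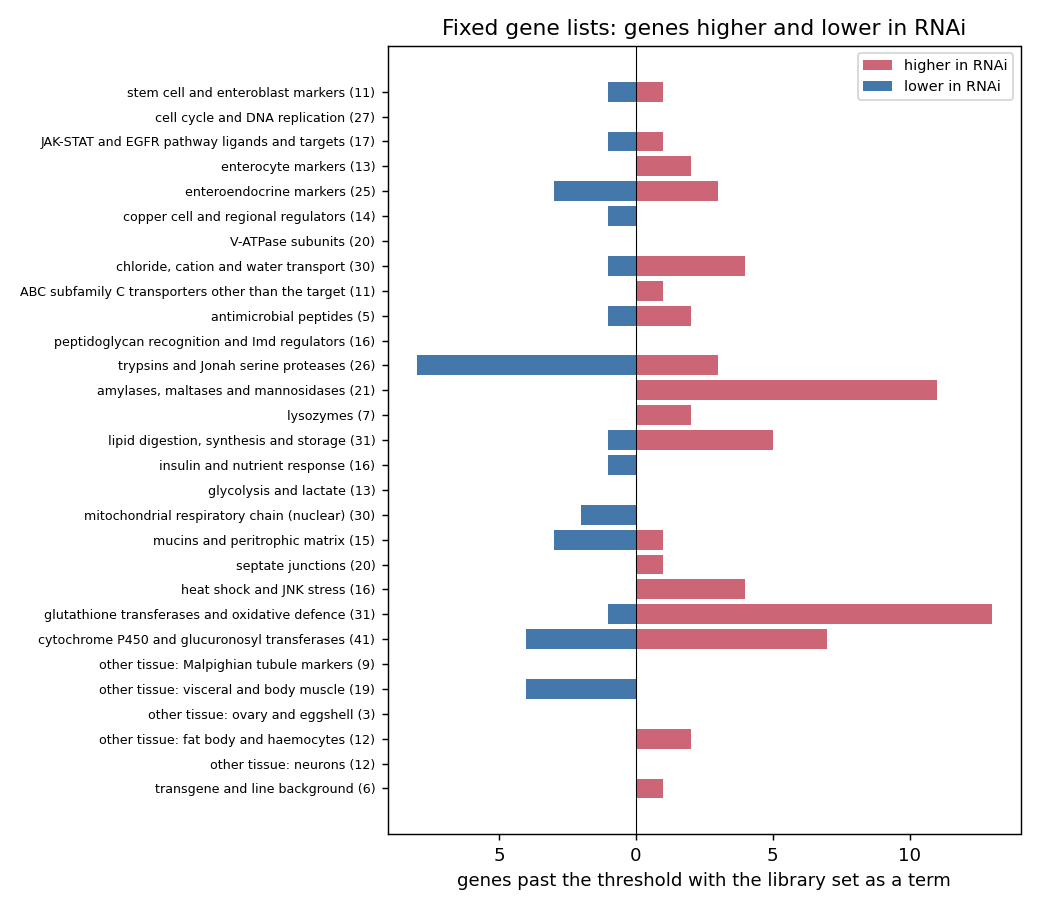
Number of genes in each fixed list with an adjusted p under 0.05 when the library set was a term, higher in RNAi to the right and lower to the left, with the number of genes tested in parentheses. Glutathione transferases and oxidative defence (13 higher, 1 lower) and carbohydrases (11 higher) extend to the right, and trypsins and Jonah proteases (8 lower, 3 higher) to the left.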

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

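The set term, thinning and length-trend settings were chosen after the data were examined, the others before. Against 10 higher and 2 lower genes, calls were 1 and 0 with upper-quartile factors and with a minimum mean of 5 CPM (349 and 199 genes at an unadjusted p under 0.05, either direction), 71 and 49 without a count filter, 53 and 32 with DESeq2, 20 and 11 with a length trend removed, 9 and 3 with limma-voom, and 10 and 1 after thinning. Of the 12 genes, limma-voom did not call Task6 (adjusted p = 0.0843), CG34451 (0.0758) and Cyp12d1-d (0.0830), and thinning lost Crys (0.0538), CR40190 (0.0544) and Cyp12d1-d (0.0631). The adjusted p-values of the 11 genes other than Hsp70Bb lay close to the threshold, at 0.0401. Leaving out a library gave 35 to 81 higher and 23 to 39 lower genes, and all 12 stayed called. With the set as a term calls were 332 and 352, with DESeq2 175 and 155, with limma-voom 382 and 417, with the length trend removed 393 and 482, and with library size alone 628 and 340 (64.9% higher against 48.5%). The median log2 fold change of all genes was 0.11 with library size alone and 0.0065 with TMM. The directions of the 9 called lists kept their sign under each scaling. With library size alone the medians of all 9 lay higher than with TMM. That of the respiratory chain was -0.11 instead of -0.21, and that of the V-ATPase -0.15 instead of -0.24.

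Of 5 higher and 4 lower lists, 3 were higher without a count filter, and 0 and 0 were called with an estimated correlation or fry, where the medians stay as they were: lysozymes 4.85, glutathione transferases and oxidative defence 0.93, carbohydrases 0.69, lipid 0.34, heat shock 0.33, respiratory chain -0.21, V-ATPase -0.24, proteases -0.40 and muscle -0.47. Leaving out a library gave 4 to 9 higher and 2 to 5 lower lists. The lipid call also ended with upper-quartile factors (median 0.32), library size alone (0.43), no count filter (0.33), a minimum mean of 5 CPM (0.13), the set term (0.17) and thinning (0.24), and the heat shock call ended without a count filter (0.29). With each library left out, medians ranged from -0.61 to -0.023 for the V-ATPase, -0.34 to 0.50 for lipid, -0.51 to 0.080 for the respiratory chain, 0.012 to 0.87 for heat shock and -0.81 to -0.12 for muscle.

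With each library left out, the log2 fold change of Cftr ranged from -1.48 to 0.20 (without wild type 2), tio from -0.96 to 0.74, LysX from -0.13 to 0.44, LysS from -0.48 to 0.049, Amyrel from -0.16 to 3.86, AttD from -1.74 to 3.88, Lip3 from -0.22 to 3.53, Gli from -0.24 to 1.52, Act87E from -1.84 to 0.47, sro from -1.03 to 1.13, Ncc69 from -0.36 to 1.35, Acp36DE from -0.33 to 1.33 and Mur18B from -4.92 to 0.69. The gene tio also turned to -0.015 with limma-voom, -0.078 with the set term and -0.026 with the length trend removed. The cause was not tested. Over the 108 named genes, values in settings with all libraries and no set term kept direction and side of the threshold in 1048 cases, passed it in 82 and lost it in 26. Only the 12 genes called without the set term could lose it, so the 1048 cases say little about how stable those calls were. Of the 26 losses, 11 came with upper-quartile factors and 9 with a minimum mean of 5 CPM. Depth limits genes such as CR40190, Cyp12d1-d, phtm and TotM, with few counts in the lower group. The labels give no replicate number shared by the genotypes, and the library numbers used here follow the order of deposit. The pairing of libraries in the fit with the set term was read from the counts. It matches that order, in which wild type 1 and RNAi 1 come first. The labels do not say that the order marks a batch or a pairing.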

Other observations

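All tests here were chosen after the data were examined, and for the length trend, library size and chromosome arms the outcome that would count for or against was set before the test was run. Genes of ecdysteroid hormone synthesis were lower in the libraries labelled RNAi. Of 5 tested enzymes of that pathway, phtm, spok, sad and shd were lower with the library set as a term, sro was not (log2 fold change 0.34, SE 0.83), none passed without that term in edgeR (4 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom), and the median without the set term was -3.01. The counts of phtm were 1 and 0 in the RNAi libraries and 51 in the wild-type libraries together, a ratio of 71.0 (exact interval 12.2 to 2857), those of spok 3 against 56 (ratio 26.0, 8.44 to 130), and shd, which makes the active hormone, fell from 16.5 and 38.4 CPM to 2.92 and 8.68 CPM. Ptth, the neuropeptide that drives the larval ecdysone gland, fell by 3.57 on the log2 scale. The family had a fry adjusted p of 0.00991 over 16 families and a camera adjusted p of 0.339 with an estimated correlation. Because the families were chosen after the data were seen, these p-values are no independent evidence of a lower level. A hypothesis that ecdysone response fell as well was tested on EcR, Eip75B, Eip74EF and br, whose median log2 fold change with the set term was 0.059. The median of those 4 genes was thus not lower, which leaves open a lower level in single genes among them.

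In other families single members passed with the set as a term. Of 31 UDP-glycosyltransferases 9 were lower and 2 higher with the set term, among them Ugt35C1, which fell by 3.26 (CPM 50.9 and 35.4 against 462 and 359). Of 10 genes named as MFS transporters 3 were lower, among them MFS12 and MFS9, with log2 fold changes of -2.06 and -2.20. Without the set term none of either family passed in edgeR (4 and 2 at an unadjusted p under 0.05, 1 and 2 by DESeq2, 0 and 0 by limma-voom), and camera gave an adjusted p = 0.421 with an estimated correlation for both. The log2 fold changes of the metallothionein MtnA, the lipid droplet dehydrogenase Ldsdh1, the elongase Elo68alpha and the phosphoenolpyruvate carboxykinase Pepck2 were -1.85, -2.08, -2.78 and -2.70, all past the threshold with the set term. CG12374 was among the most abundant transcripts, at 65400 CPM in wild type 2 against 28414 CPM in RNAi 2, and fell by 1.56. Of 83 cytosolic ribosomal protein genes 78 were lower in both sets, with a median log2 fold change of -0.33, or -0.23 with library size alone, and 1 passed with the set term; the family was also lower in set 2 than in set 1 (camera adjusted p = 5.32e-21).

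The libraries formed 2 sets that cut across the genotypes. Between the sets 1992 genes passed in edgeR, against 12 between the genotypes without the set term and 684 with it. The sets were read from the leading principal component of the same counts, which favours a large number. The number is therefore no test of a structure of the libraries. After thinning to the smallest total 1931 passed, which argues against library size as the cause. With a trend on transcript length removed per library 135 passed, and the log2 ratio of set 2 to set 1 correlated with length across genes (Spearman's rho 0.519). A difference in RNA integrity or library preparation that acts by length is thus a candidate explanation for most of these calls. A count of calls does not show how much of the whole difference between the sets it covers. No biological explanation for the sets was tested, since the labels give none.

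Of the 3 ways to split 4 libraries into pairs, 2 gave at least 12 genes, and the highest of the others was the 1992 of the set split, while the third gave 0 in edgeR, DESeq2 and limma-voom (48 at an unadjusted p under 0.05 in edgeR); 3 splits are too few for a share under 0.05.

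Cftr was not lower in RNAi 1 than in wild type 1. An exchange of a wild-type library with the RNAi library of the same set is argued against by the crossed split, which with the set term gave 0 calls in edgeR (67 at an unadjusted p under 0.05) against 684. After an exchange with the RNAi library of the other set the sets would be the genotypes. Cftr had a log2 fold change, set 2 relative to set 1, of 1.13 (SE 0.45, edgeR adjusted p = 0.146). Cftr by itself leaves such an exchange open. The 12 genes called between the labelled genotypes, among them Hsp70Bb, would then differ between the libraries of each genotype. Because these genes were picked by the labels, they were not used to test it. A lower level hidden by the difference between sets is open too, since the ratio of 1.01 within set 1 rests on 1 library against 1, and with the spread of the fit with the set term its interval starts at 0.517. What stays open and untested is a knockdown confined to some cells of the gut, counts from the RNAi hairpin itself, and a level in wild type 2 raised for another reason.

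Counts of Hsp70Bb were 3 and 1 in wild type and 1230 and 919 in the RNAi libraries. A general heat-shock response as the whole cause is argued against by the other 9 heat-shock and co-chaperone genes, whose median log2 fold change was 0.41, although Hsp83 and stv rose. Reads from an RNAi transgene that carries heat-shock gene sequence may also be counted as Hsp70Bb. The marker gene w was higher within both sets, by log2 ratios of 0.68 and 0.84. This carries little weight, since 30.5% of all tested genes were higher within both sets. Gene counts do not show which part of Hsp70Bb the reads cover, so transgene sequence and transcription of the native gene cannot be told apart.

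A hypothesis that the genotypes differ in the background of 1 chromosome was tested on the 684 genes called with the set term. The highest share relative to that expected was 1.09, on arm 2R, which argues against calls gathered on 1 arm. The X chromosome was at 0.801 times the expected share (Fisher's exact test, adjusted p = 0.0981). A background that differs on all arms would not raise the share of 1 arm, so this test leaves it open. Called genes did lie side by side: 71 adjacent pairs were called in the same direction, against a median of 24 and a maximum of 41 in 1000 permutations of gene order, with a permutation p of 0.001, the smallest these can give. Tandem gene families such as the GstD cluster, reads shared among them, and short stretches of differing line background could each give such pairs and were not separated.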
